A study of Homo sapiens with 8 samples.

How the data were processed

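The data were droplet single-cell RNA libraries made with 10x 3' v2 chemistry from human cells, 8 in all. Per the labels, 2 libraries each were SW480 monolayer, SW480 spheroid and SW480 vascularized micro-tumour (VMT), and 1 each was HCT116 monolayer and HCT116 VMT. Groups were taken from the source label and never changed from the values. Per the labels' protocol, VMT chambers were treated with TrypLE and then collagenase, and cells were passed through a 70 µm filter and sorted as live cells. The deposited values were raw unique molecular identifier (UMI) counts per gene and cell barcode. Per the submitters' processing notes, the counts came from Cell Ranger, for which no version is given, and R 3.6.0 and Seurat 2.3.4 were also used. Those notes name the builds GRCh38 and hg19 without saying which applies to which step, so no coordinates are given here. Each matrix held 33694 gene rows, of which 33132 identifiers were in the reference annotation (GENCODE v29) and 562 were not. The annotation was used for gene type, chromosome and transcript length only. Gene symbols were those paired with the identifiers in the deposited files.

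Libraries held 826 to 5530 barcodes and 34136564 to 132448494 UMIs. Scrublet, as run in scanpy 1.11.5 in each library, called 0 to 124 barcodes per library doublets, and these were removed. Cells with under 500 genes or over 20% mitochondrial UMIs were removed as well, 0 to 16 per library. The removal took effect when cells were counted and UMIs were summed. The clustering used all barcodes, doublet calls and cells that failed the filter included. Barcodes were scaled to a total of 10000 and log-transformed, and 2000 variable genes and 30 principal components were taken. Cells were joined to 15 neighbours and clustered with the Leiden method at resolution 0.5, all libraries together and with fixed seeds. Clusters were named from markers fixed before the data were examined: 32 for tumour epithelial, 24 for fibroblast, 24 for endothelial and 14 for immune cells. A class needed a marker sum of 500 CPM (UMIs scaled to a common total) and 3 markers at 10 CPM. The next class had to stay under 0.25 of the first, and a cluster with over 50% doublet calls was not named. These thresholds were set after the clusters had been seen. The names tumour-like, fibroblast-like and endothelial-like rest on these markers and not on a label of each cell. The share of free RNA, estimated from markers of other classes, was 1.11 to 4.37% in the libraries with stroma. It was not subtracted in the main results. A gene at 10 or more times the level in another class of the same libraries was counted apart. Genes with near-identical copies, among them HSPA1A and HSPA1B, SAA1 and SAA2, and the MT1 and MT2 genes, may share reads with their copies.

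UMI counts were summed per library over the cells of a class, with at least 20 cells per sum. Sums held 519 to 1272 tumour-like, 185 to 758 fibroblast-like and 122 to 607 endothelial-like cells in the SW480 monolayer and VMT libraries. They were tested with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F test, two-sided) in R 4.3.3. All 6 SW480 libraries entered 1 tumour-like fit, and the 4 monolayer and VMT libraries entered a fit for each stromal class. The p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 0.166 in the tumour-like fit, 0.133 in the fibroblast-like fit and 0.152 in the endothelial-like fit, and residual degrees of freedom were 3, 2 and 2. The prior degrees of freedom, borrowed across genes, were 4.34, 6.16 and 90.2 in that order. Among tested genes, 74.5% had both VMT libraries apart from both monolayer libraries in tumour-like cells, where a random order of the 4 libraries gives 33.3%. The share was 62.7% for spheroid and monolayer, 80.1% for VMT and spheroid, 72.9% in fibroblast-like and 71.3% in endothelial-like cells. These shares used CPM without the TMM factors, which differed between groups. A difference of scale alone can set groups apart, so the shares do not measure how many genes changed. Where a group had 1 to 3 UMIs the ratio is given with an exact interval, and where it had none the bound is over a group floor of 3 counts. These intervals and floors cover counting error only.

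The 23 gene lists were fixed before the data were examined, 10 of them for every class. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Differences of lists between classes were tested with camera on the class by culture interaction, with library in the model. Setting members without a UMI in a group to their bound moved the median of no list, and 2 of the 69 list tests had such a member. The libraries labelled HCT116 had 1 library per group and no test. There list medians were ranked among 10000 random lists matched in 20 bins of expression. Shares of cells had exact binomial intervals and an exact permutation test. The rule for named genes was fixed before the data were examined. The largest changes were named among genes with an adjusted p below 0.05, a 2-fold change, at least 50 CPM in the higher group, groups that did not overlap and under 10 times the level in another class. Sex-linked marker, mitochondrially encoded, ribosomal protein, clone-named and pseudogene entries were left out. Of these, the 10 largest rises and 10 largest falls per comparison could be named. From each list, up to 4 members with the smallest adjusted p could be named as well, without those minimums of change, level or class. Some genes that this rule or the check of the labels would name are not reported here. For the libraries labelled HCT116 the 5 largest changes each way at 50 CPM and 100 UMIs could be named.

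The procedure was tested on simulated counts with 200 changed genes, all drawn from genes at 10 CPM or more in the reference group. The simulated counts held no difference between library preparations. The rates below therefore do not cover tested genes at lower levels. Of 4-fold changes 100% were recovered in all 5 comparisons. Of 2-fold changes, 69% were recovered for VMT against monolayer tumour-like cells (14806 genes), 68% for spheroid against monolayer (14809) and 70% for VMT against spheroid (14487). In fibroblast-like cells 87% (11830 genes) and in endothelial-like cells 78% (11268 genes) were. Unchanged genes called numbered 9, 5, 4, 7 and 12 in that order. The alternatives were DESeq2 1.42.0, its size factors in edgeR, other filters on genes and cells, doublet calls kept, classes from each cell's own markers, free RNA subtracted, equal cells per library, each library left out, a replicate block, fits of only the groups compared and a library set covariate. Fits of each tumour-like population, without clusters of low UMI content, with the library set covariate for lists, without genes that differ between the monolayer libraries, and without the second monolayer and spheroid libraries were added after the data had been seen. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used.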

Results

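Single-cell RNA was measured in 8 droplet libraries made with 10x 3' v2 chemistry. In 6 of them, cells of a colorectal cancer line were together with cells labelled NHLF and EPC, which the labels do not spell out. The monolayer libraries held the 3 kinds of cell grown apart and pooled before capture. The vascularized micro-tumour (VMT) libraries held cells grown in contact in the tissue chambers of a device, and the spheroid libraries held cancer cells only. By the source label, 2 libraries each were SW480 monolayer, SW480 spheroid and SW480 VMT, and 1 library each was HCT116 monolayer and HCT116 VMT. SW480 and HCT116 are established human colorectal cancer lines. For the 4 SW480 monolayer and VMT libraries a further label names HCT116 as the cancer line, so the line is uncertain there. The spheroid libraries are SW480 in both labels. By the labels alone, a difference of line cannot be told apart from culture in the comparisons with spheroids. The SW480 monolayer libraries held 47670236 and 54494628 unique molecular identifiers (UMIs), the spheroids 47564386 and 55975268, and the VMT libraries 39789958 and 34136564. The libraries labelled HCT116 held 132448494 (monolayer) and 49053095 (VMT). The median depth per barcode was 13975 to 21758 UMIs in monolayers and spheroids and 32375 to 36997.5 in the VMT libraries.

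Tumour-like, fibroblast-like and endothelial-like cells were told apart by fixed markers. Epithelial genes such as EPCAM, collagen genes such as COL1A1, and vessel genes such as PECAM1 and CDH5 each marked separate clusters. Tumour-like cells made up 62.7% ± 0.186 (SD, n = 2) of the cells of the SW480 VMT libraries and 47.7% ± 2.5 of the monolayer mixes. Fibroblast-like cells made up 22.7% ± 0.491 and 28.7% ± 1.02, and endothelial-like cells 14.6% ± 0.305 and 22.3% ± 1.82. The exact permutation test, two-sided, gave p = 0.333 for each class, the smallest p this design allows. The shares of the monolayers were set by the mixing. All 2436 and 3595 spheroid cells were tumour-like, and 0 stromal cells in them allow a share of up to 0.123% and 0.0834% (3 cells of the total). No cluster carried immune genes such as PTPRC or CD68 at the naming minimum, and the 14 immune markers summed to 5.9 to 203.5 CPM per cluster. The thresholds for naming clusters were set after the clusters had been seen. They left 25.7% of the cells of the VMT library labelled HCT116 (exact binomial 95% interval 23.2 to 28.3%) and 2.52% of SW480 monolayer library 1 without a class. In the other libraries 0 to 0.117% stayed unnamed. In the fibroblast-like and endothelial-like classes, most cells of the SW480 VMT and SW480 monolayer libraries lay in different clusters. Some tumour-like clusters were shared between cultures, and others lay mostly in 1 culture. A cluster with 222 and 200 barcodes of the SW480 VMT libraries also held 921 and 1253 of the spheroids. Another with 158 and 118 barcodes of the SW480 VMT libraries held 881 and 903 of the SW480 monolayers. By contrast, a cluster with 140 and 100 barcodes of the SW480 VMT libraries held 6 and 5 of the SW480 monolayers and 8 and 7 of the spheroids. One with 964 and 1512 barcodes of the spheroids held 23 and 41 of the SW480 monolayers and 19 and 12 of the SW480 VMT libraries.

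**Figure D1:**
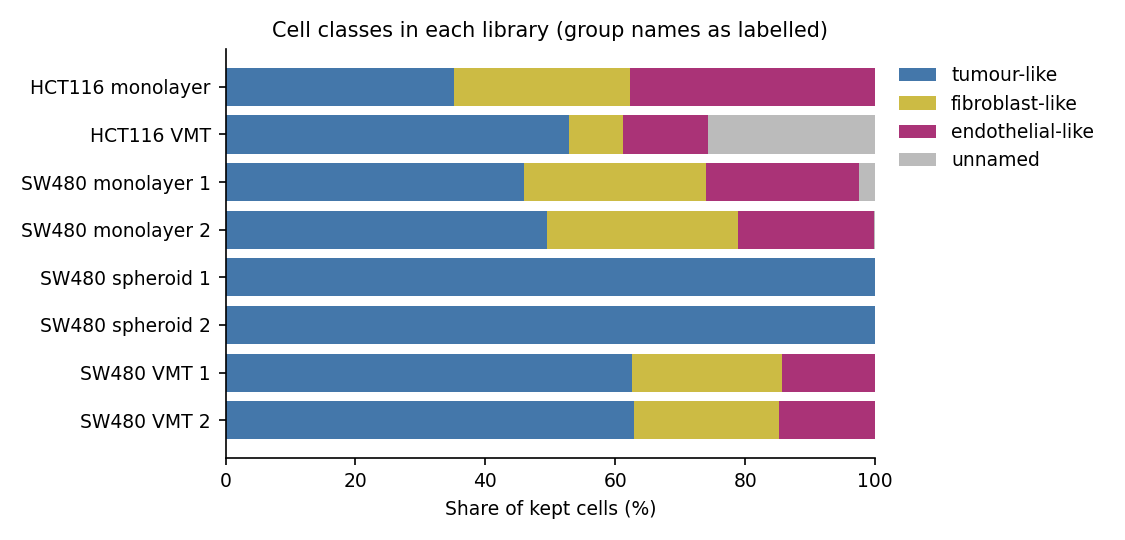
Share of kept cells in each class (x axis, percent) in each of the 8 libraries (y axis), as stacked horizontal bars coloured by class. The tumour-like share of the SW480 VMT libraries was 62.7% ± 0.186 against 47.7% ± 2.5 in the monolayer mixes, and 25.7% of the cells of the VMT library labelled HCT116 had no named class.

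In the comparisons that follow, levels are mean CPM ± SD over the 2 libraries of a group. Changes are fitted log2 fold changes ± standard error from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p-values. List tests are by camera. The labels number the libraries as replicates without saying that they came from separate cultures, so all p-values measure only the spread between these libraries. The fits pooled that spread over groups, although it differed between them. In tumour-like cells the chi-square per degree of freedom between the libraries of a group was 26.9 for monolayers, 50.1 for spheroids and 4.94 for the VMT. This measure also grows with depth. The estimate of that spread borrowed 90.2 degrees of freedom across genes in the endothelial-like fit. It borrowed 4.34 in the tumour-like and 6.16 in the fibroblast-like fit, so the sizes of p-values cannot be compared between classes.

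The first question was how SW480 tumour-like cells in the VMT differed from the same line in monolayer. Genes switched on within minutes of a stimulus were higher in the VMT. FOS (ENSG00000170345), a subunit of the AP-1 transcription factor, stood at 207 ± 13.5 against 29.1 ± 4.02 CPM (log2 fold change 2.55 ± 0.15, adjusted p = 0.00142). JUN and JUNB, its partners, rose by 2.25 ± 0.15 and 1.86 ± 0.12, and TXNIP, a glucose-regulated inhibitor of thioredoxin, rose by 3.65 ± 0.30. LCN2, an iron-scavenging lipocalin, stood at 56.9 ± 2.02 against 519 ± 107 CPM and fell by 3.49 ± 0.27. CLDN7, a tight-junction claudin, fell by 2.24 ± 0.17, and the largest falls also held BEX2 and the long non-coding RNAs EPB41L4A-AS1 and SNHG8. In all, 3802 of 15404 genes changed, 2051 higher and 1751 lower in the VMT, and 1713 of them by 2-fold or more.

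Of the immediate early and heat shock genes, 26 of 30 rose, 1 fell and 3 did not pass (26 rose and 1 fell adjusted over the list alone). The immediate early and heat shock list had a median log2 change of 1.41 (adjusted p = 1.18e-30, and adjusted p = 0.0133 with an estimated correlation). Cells of the VMT were freed with TrypLE and collagenase per the labels' protocol, which does not describe how the monolayers were detached. Of the proliferation genes, 33 of 40 rose, 1 fell and 6 did not pass (37 rose and 1 fell adjusted over the list alone). The proliferation list had a median log2 change of 1.24 (adjusted p = 1.96e-24, and adjusted p = 0.112 with an estimated correlation). PLK1, a mitotic kinase, rose by 1.88 ± 0.17, and CDK1, the kinase that starts mitosis, by 1.77 ± 0.12. Of the cholesterol synthesis genes, 17 of 26 rose, 0 fell and 9 did not pass (20 rose and 0 fell adjusted over the list alone). The cholesterol synthesis list had a median log2 change of 0.98 (adjusted p = 2.15e-11, and adjusted p = 0.165 with an estimated correlation). HMGCS1, an early enzyme of that pathway, rose by 1.75 ± 0.16, and IDI1, a later one, by 1.62 ± 0.16. Of the NF-kB and chemokine genes, 10 of 22 rose, 2 fell and 10 did not pass (10 rose and 3 fell adjusted over the list alone). The NF-kB and chemokine list had a median log2 change of 0.83 (adjusted p = 8.15e-06, and adjusted p = 0.165 with an estimated correlation). The neutrophil attractants CXCL8 and CXCL6 rose by 1.78 ± 0.17 and 2.00 ± 0.20. Of the interferon response genes, 19 of 38 rose, 3 fell and 16 did not pass (23 rose and 3 fell adjusted over the list alone). The interferon response list had a median log2 change of 0.76 (adjusted p = 2.04e-06, and adjusted p = 0.165 with an estimated correlation). IFI6 rose by 1.53 ± 0.15 and IFI27 fell by 1.64 ± 0.17. Of the Wnt target and intestinal stem genes, 12 of 30 rose, 1 fell and 17 did not pass (13 rose and 1 fell adjusted over the list alone). The Wnt targets and intestinal stem list had a median log2 change of 0.50 (adjusted p = 0.00114, and adjusted p = 0.165 with an estimated correlation). BMP4, a secreted growth factor, rose by 1.15 ± 0.12, and the Wnt inhibitor DKK1 rose as well. The stem cell receptor LGR5 had 2 UMIs in the monolayers and 41 in the VMT, a ratio of 18.0 (exact 95% interval 4.67 to 153). The 1 list that fell was ATF4 and unfolded protein response. Of the ATF4 and unfolded protein response genes, 1 of 32 rose, 12 fell and 19 did not pass (3 rose and 15 fell adjusted over the list alone). The ATF4 and unfolded protein response list had a median log2 change of −0.37 (adjusted p = 5.20e-05, and adjusted p = 0.272 with an estimated correlation). In it MTHFD2, a mitochondrial folate enzyme, fell by 1.08 ± 0.13 and MANF, a secreted stress protein, by 0.95 ± 0.14. The other 6 lists did not pass. Of the hypoxia and glycolysis genes, 7 of 35 rose and 7 fell (8 and 10 adjusted over the list alone), with median −0.08 and adjusted p = 0.577. Of the TGF-beta response genes, 3 of 30 rose and 4 fell (3 and 2 adjusted over the list alone), with median 0.02 and adjusted p = 0.661, its test pointing down. Of the p53 targets, 6 of 25 rose and 4 fell (6 and 4 adjusted over the list alone), with median 0.08 and adjusted p = 0.661. Of the oxidative phosphorylation genes, 9 of 51 rose and 3 fell (8 and 2 adjusted over the list alone), with median 0.18 and adjusted p = 0.247. Of the mesenchymal state genes, 12 of 28 rose and 3 fell (12 and 4 adjusted over the list alone), with median 0.27 and adjusted p = 0.19. Without the genes abundant in another class that list passed and rose (adjusted p = 0.00108, range over its alternatives 0.00108 to 0.293). Of the epithelial junction and colonic differentiation genes, 11 of 34 rose and 3 fell (14 and 3 adjusted over the list alone), with median 0.42 and adjusted p = 0.0869.

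Ribosomal protein genes took 35.6 and 37.9% of the tumour-like UMIs in the monolayers, 30.9 and 33.4% in the spheroids and 26.1 and 26.6% in the VMT libraries. Fitted changes use the TMM factors and CPM does not, so ratios of CPM and fitted changes differ. Against the same-numbered monolayer, the TMM factor was lower in each spheroid library and higher in each VMT library. Whether the ribosomal share accounts for these factors was not tested. Of the called genes, 132 had at least 10 times the level in another class, among them IFI27. The count fell to 359 and 316 without VMT library 1 and 2 and to 2257 without monolayer library 2. Of the 68 named genes, 48 and 43 kept their call without VMT library 1 and 2, and MTHFD2 and MANF lost it both times. Tumour-like clusters were parted into 2 populations by the correlation of their profiles, and in the second alone 1966 genes were called. There CDK1 and DKK1 turned to −0.27 and −0.73, CXCL8, IFI6 and BMP4 were 0.36, 0.73 and 0.59 and no longer passed, and the interferon list gave adjusted p = 0.165 (range over its alternatives 6.34e-08 to 0.165). In the first population alone LCN2 was −0.87 and IFI27 −0.65, and neither passed. Without the second monolayer and spheroid libraries 6988 genes were called.

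**Figure D2:**
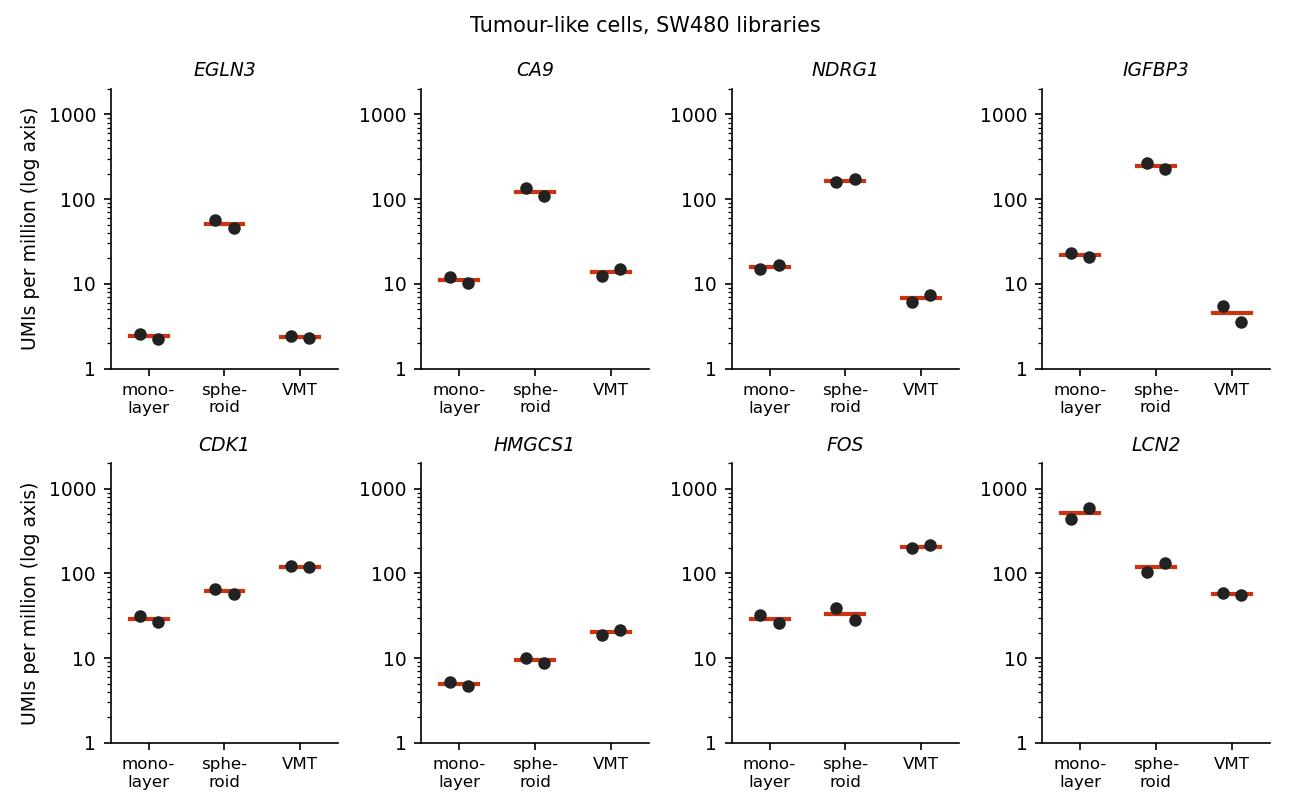
Level of 8 genes in SW480 tumour-like cells (y axis, CPM on a log scale) in each monolayer, spheroid and VMT library (x axis), with points for libraries and red bars for group means. EGLN3, CA9, NDRG1 and IGFBP3 were highest in both spheroids, FOS was highest in both VMT libraries, and LCN2 was highest in both monolayers.

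The spheroids, which hold cancer cells alone in 3 dimensions, were compared with the monolayers next. Genes of the response to low oxygen were higher in the spheroids. EGLN3 (ENSG00000129521), an oxygen-sensing prolyl hydroxylase, stood at 51.2 ± 8.72 against 2.39 ± 0.234 CPM (log2 fold change 4.55 ± 0.17, adjusted p = 9.03e-05). CA9, a carbonic anhydrase that controls pH, stood at 123 ± 17.5 against 11.1 ± 1.27 CPM, and PGK1, a glycolytic enzyme, at 985 ± 35.4 against 123 ± 11.4 CPM. TFF3, a mucosal repair peptide, rose by 2.77 ± 0.14, and IGFBP3, which TGF-beta is known to induce, rose by 3.62 ± 0.19. SLPI, a secreted protease inhibitor, fell by 2.32 ± 0.15, and SDF2L1, a chaperone cofactor of the endoplasmic reticulum, by 1.55 ± 0.16. In all, 4751 of 15404 genes changed, 2592 higher and 2159 lower in the spheroids, and 2292 by 2-fold or more.

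Of the hypoxia and glycolysis genes, 32 of 35 rose, 1 fell and 2 did not pass (32 rose and 1 fell adjusted over the list alone). The hypoxia and glycolysis list had a median log2 change of 1.97 (adjusted p = 1.07e-57, and adjusted p = 0.0216 with an estimated correlation). NDRG1, a stress gene of poorly oxygenated cells, stood at 166 ± 7.44 against 15.8 ± 1.35 CPM. Of the immediate early and heat shock genes, 19 of 30 rose, 0 fell and 11 did not pass (20 rose and 0 fell adjusted over the list alone). The immediate early and heat shock list had a median log2 change of 0.78 (adjusted p = 2.88e-13, and adjusted p = 0.0216 with an estimated correlation). The chaperones HSPA1A, DNAJB1 and HSP90AA1 rose by 4.81 ± 0.19, 2.48 ± 0.13 and 1.65 ± 0.14. Another 6 lists rose with the preset correlation only. Of the proliferation genes, 21 of 40 rose, 1 fell and 18 did not pass (21 rose and 1 fell adjusted over the list alone). The proliferation list had a median log2 change of 0.77 (adjusted p = 1.35e-06, and adjusted p = 0.218 with an estimated correlation). RRM2, which makes deoxynucleotides, rose by 1.59 ± 0.15. Of the Wnt target and intestinal stem genes, 15 of 30 rose, 1 fell and 14 did not pass (16 rose and 1 fell adjusted over the list alone). The Wnt targets and intestinal stem list had a median log2 change of 0.71 (adjusted p = 3.27e-05, and adjusted p = 0.0839 with an estimated correlation). AXIN2, a feedback inhibitor of Wnt signalling, rose by 1.59 ± 0.15. Of the cholesterol synthesis genes, 12 of 26 rose, 2 fell and 12 did not pass (13 rose and 2 fell adjusted over the list alone). The cholesterol synthesis list had a median log2 change of 0.54 (adjusted p = 0.00137, and adjusted p = 0.426 with an estimated correlation). INSIG1, a sterol sensor, rose by 1.81 ± 0.16. Of the TGF-beta response genes, 15 of 30 rose, 5 fell and 10 did not pass (16 rose and 6 fell adjusted over the list alone). The TGF-beta response list had a median log2 change of 0.57 (adjusted p = 0.00137, and adjusted p = 0.116 with an estimated correlation). Of the mesenchymal state genes, 14 of 28 rose, 3 fell and 11 did not pass (14 rose and 4 fell adjusted over the list alone). The mesenchymal state list had a median log2 change of 0.69 (adjusted p = 0.0139, and adjusted p = 0.168 with an estimated correlation). The integrin subunit ITGA5 rose by 2.05 ± 0.17. Of the epithelial junction and colonic differentiation genes, 10 of 34 rose, 6 fell and 18 did not pass (10 rose and 6 fell adjusted over the list alone). The epithelial junction and colonic differentiation list had a median log2 change of 0.20 (adjusted p = 0.0397, and adjusted p = 0.26 with an estimated correlation). TFF3 and the claudin CLDN4 were among those that rose, and ESRP1, a splicing factor of epithelial cells, fell by 1.24 ± 0.15. The other 5 lists did not pass. Of the interferon response genes, 6 of 38 rose and 1 fell (5 and 1 adjusted over the list alone), with median 0.22 and adjusted p = 0.378. Of the NF-kB and chemokine genes, 7 of 22 rose and 2 fell (7 and 2 adjusted over the list alone), with median 0.05 and adjusted p = 0.0958. Of the ATF4 and unfolded protein response genes, 5 of 32 rose and 7 fell (5 and 8 adjusted over the list alone), with median −0.21 and adjusted p = 0.0713. With a replicate block that list passed and fell (adjusted p = 0.0448, range over its alternatives 0.000777 to 0.565). Of the p53 targets, 7 of 25 rose and 1 fell (7 and 2 adjusted over the list alone), with median 0.22 and adjusted p = 0.197. Of the oxidative phosphorylation genes, 9 of 51 rose and 0 fell (4 and 0 adjusted over the list alone), with median 0.13 and adjusted p = 0.208.

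Of the called genes, 139 had at least 10 times the level in a stromal class of the monolayer libraries, and all of these were lower in the spheroids. That direction was fixed by the rule, which looked at the group with the higher level, since the spheroids held no stromal cells. Leaving such genes out therefore took out genes of 1 direction only. The count fell to 3038 without spheroid library 1, to 3072 with equal cells per library and to 2996 in the second tumour-like population alone. In that population the mesenchymal list gave adjusted p = 0.509 (range over its alternatives 9.55e-07 to 0.509). The epithelial list gave 0.28 there, 0.0761 in the first population and 0.0502 without the genes abundant in another class (range 0.00402 to 0.28).

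The VMT and the spheroids, the 3-dimensional cultures with and without stroma, were then compared directly. The low-oxygen genes separated them. IGFBP3 stood at 4.55 ± 1.37 against 246 ± 28.2 CPM, EGLN3 at 2.34 ± 0.0822 against 51.2 ± 8.72 CPM, and BNIP3L, a receptor for the removal of mitochondria, at 21.8 ± 0.251 against 197 ± 13.7 CPM. Their log2 fold changes were −6.17 ± 0.21, −4.87 ± 0.17 and −3.60 ± 0.13 (adjusted p = 3.22e-05 for each). The metal-binding MT1X fell by 3.22 ± 0.16 and TFF3 by 3.37 ± 0.15. FOS stood at 207 ± 13.5 against 33.3 ± 7.62 CPM and rose by 2.22 ± 0.15, its relative FOSB rose by 2.48 ± 0.22, and the chemokine CXCL3 rose by 1.53 ± 0.22. In all, 5161 of 15404 genes changed, 2448 higher and 2713 lower in the VMT, and 2292 by 2-fold or more.

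Of the hypoxia and glycolysis genes, 1 of 35 rose, 34 fell and 0 did not pass (1 rose and 34 fell adjusted over the list alone). The hypoxia and glycolysis list had a median log2 change of −2.21 (adjusted p = 4.18e-60, and adjusted p = 0.0341 with an estimated correlation). Of the TGF-beta response genes, 5 of 30 rose, 15 fell and 10 did not pass (8 rose and 17 fell adjusted over the list alone). The TGF-beta response list had a median log2 change of −0.61 (adjusted p = 0.00123, and adjusted p = 0.193 with an estimated correlation). IGFBP3 was among those that fell. Of the proliferation genes, 17 of 40 rose, 1 fell and 22 did not pass (19 rose and 2 fell adjusted over the list alone). The proliferation list had a median log2 change of 0.58 (adjusted p = 0.000346, and adjusted p = 0.466 with an estimated correlation). MCM7 and MCM5, parts of the replicative helicase, rose by 1.04 ± 0.12 and 1.09 ± 0.15. Of the interferon response genes, 18 of 38 rose, 3 fell and 17 did not pass (19 rose and 4 fell adjusted over the list alone). The interferon response list had a median log2 change of 0.58 (adjusted p = 0.000889, and adjusted p = 0.466 with an estimated correlation). MX1, an antiviral GTPase, rose by 2.61 ± 0.26. Of the cholesterol synthesis genes, 9 of 26 rose, 2 fell and 15 did not pass (11 rose and 2 fell adjusted over the list alone). The cholesterol synthesis list had a median log2 change of 0.43 (adjusted p = 0.0198, and adjusted p = 0.504 with an estimated correlation). Of the NF-kB and chemokine genes, 8 of 22 rose, 4 fell and 10 did not pass (11 rose and 4 fell adjusted over the list alone). The NF-kB and chemokine list had a median log2 change of 0.46 (adjusted p = 0.0421, and adjusted p = 0.485 with an estimated correlation). Of the immediate early and heat shock genes, 13 of 30 rose, 7 fell and 10 did not pass (14 rose and 7 fell adjusted over the list alone). The immediate early and heat shock list had a median log2 change of 0.33 (adjusted p = 0.0231, and adjusted p = 0.271 with an estimated correlation). FOS and FOSB were among those that rose, while the chaperones HSPA1B and DNAJB1 fell by 2.11 ± 0.19 and 1.53 ± 0.12. The other 6 lists did not pass. Of the ATF4 and unfolded protein response genes, 4 of 32 rose and 11 fell (4 and 12 adjusted over the list alone), with median −0.23 and adjusted p = 0.13. Of the p53 targets, 2 of 25 rose and 9 fell (4 and 10 adjusted over the list alone), with median −0.06 and adjusted p = 0.359. Of the oxidative phosphorylation genes, 4 of 51 rose and 2 fell (0 and 0 adjusted over the list alone), with median −0.04 and adjusted p = 0.874. Of the Wnt target and intestinal stem genes, 4 of 30 rose and 8 fell (4 and 8 adjusted over the list alone), with median −0.21 and adjusted p = 0.212. Of the mesenchymal state genes, 4 of 28 rose and 7 fell (6 and 7 adjusted over the list alone), with median −0.37 and adjusted p = 0.289. Of the epithelial junction and colonic differentiation genes, 5 of 34 rose and 6 fell (5 and 6 adjusted over the list alone), with median 0.07 and adjusted p = 0.673, its test pointing down.

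Of these libraries only those of the VMT held stromal cells, and all 108 called genes with at least 10 times the level in a stromal class were higher there. The rule looked at the group with the higher level, so it could not count a gene higher in the spheroids, and that direction was fixed. The count was 1185 and 1465 without VMT library 1 and 2, 2902 without spheroid library 2, 2862 in the second tumour-like population alone and 8746 without the second monolayer and spheroid libraries. In the first population alone the NF-kB list gave adjusted p = 0.293, and 0.0604 in all tumour-like cells without the genes abundant in a stromal class (range over its alternatives 0.00202 to 0.485). The first population gave the TGF-beta list an adjusted p = 0.104 (range 4.35e-11 to 0.193), and the immediate early list gave 0.146 in the second population and 0.0816 without the second monolayer and spheroid libraries (range 0.00364 to 0.271).

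To set both 3-dimensional cultures against the monolayer together, genes called in both comparisons were counted. There were 851 genes higher in both VMT and spheroid, among them HSPA1A, TXNIP, CDK1 and HMGCS1, where independent lists of these sizes would share 345. There were 770 lower in both, among them LCN2 and BEX2, where independent lists would share 245. Another 171 went opposite ways. Of these, 61 were higher in the VMT and lower in the spheroid, and 110, among them NDRG1 and IGFBP3, were lower in the VMT and higher in the spheroid. In the first tumour-like population alone, NDRG1 and IGFBP3 were 0.26 and 0.58 on the log2 scale in the VMT against the monolayer. The comparisons share their monolayer libraries, so part of the overlap can come from those libraries. Across genes, which are not independent replicates, the changes in the comparisons correlated at 0.446 with a covariance of 0.325. In 20 simulations without a change, all libraries were redrawn around the monolayer mean, and both comparisons used the same simulated monolayers. They gave a mean correlation of 0.559 and a mean covariance of 0.0698. The simulations left out the deviation shared by same-numbered monolayer and spheroid libraries. They therefore cannot show how much of the overlap came from shared libraries. With a 2-fold minimum as well, 643 genes went the same way.

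In fibroblast-like cells, secreted signals and matrix genes were higher in the VMT than in the monolayer. CXCL8 (ENSG00000169429), which attracts neutrophils, stood at 1744 ± 175 against 10.7 ± 0.576 CPM (log2 fold change 7.08 ± 0.16, adjusted p = 4.20e-07), and IL11, a cytokine of fibrosis, at 86.9 ± 30.4 against 0.867 ± 0.092 CPM. MMP3, a protease that degrades matrix, had 2 UMIs in the monolayers and 1339 in the VMT, a ratio of 1260 (exact 95% interval 348 to 10400). COL4A1, a chain of basement membrane collagen, stood at 175 ± 21.1 against 8.83 ± 1.24 CPM. FABP4, a fatty acid carrier, stood at 6.3 ± 1.15 against 173 ± 4.3 CPM and fell by 5.04 ± 0.16, and SFRP1, a secreted Wnt inhibitor, fell by 2.87 ± 0.14. In all, 3918 of 12416 genes changed, 2094 higher and 1824 lower in the VMT, and 1793 by 2-fold or more.

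Of the inflammatory fibroblast genes, 18 of 22 rose, 1 fell and 3 did not pass (18 rose and 1 fell adjusted over the list alone). The inflammatory fibroblast list had a median log2 change of 4.59 (adjusted p = 4.41e-54, and adjusted p = 0.032 with an estimated correlation). CXCL5, another neutrophil attractant, stood at 146 ± 19.8 against 0.178 ± 0.0319 CPM. Of the NF-kB and chemokine genes, 18 of 24 rose, 0 fell and 6 did not pass (20 rose and 0 fell adjusted over the list alone). The NF-kB and chemokine list had a median log2 change of 3.11 (adjusted p = 1.07e-47, and adjusted p = 0.032 with an estimated correlation). Several of its genes are also in the inflammatory list, and the antioxidant enzyme SOD2 rose by 3.10 ± 0.11. Of the ATF4 and unfolded protein response genes, 30 of 32 rose, 0 fell and 2 did not pass (30 rose and 0 fell adjusted over the list alone). The ATF4 and unfolded protein response list had a median log2 change of 1.67 (adjusted p = 3.46e-31, and adjusted p = 0.0352 with an estimated correlation). In it SLC7A11, a cystine importer, rose by 3.93 ± 0.16, and HSPA5, the main chaperone of the endoplasmic reticulum, by 2.36 ± 0.13. Of the matrix and basement membrane genes, 33 of 44 rose, 5 fell and 6 did not pass (35 rose and 5 fell adjusted over the list alone). The matrix and basement membrane list had a median log2 change of 1.04 (adjusted p = 8.24e-20, and adjusted p = 0.032 with an estimated correlation). The collagen genes COL4A2 and COL5A3 rose by 2.74 ± 0.13 and 4.26 ± 0.22. Of the TGF-beta response genes, 19 of 29 rose, 4 fell and 6 did not pass (22 rose and 4 fell adjusted over the list alone). The TGF-beta response list had a median log2 change of 1.57 (adjusted p = 8.53e-21, and adjusted p = 0.032 with an estimated correlation). INHBA, the activin A subunit, rose by 3.68 ± 0.14 and ID3 by 3.68 ± 0.16. Of the matrix proteases and inhibitors, 14 of 25 rose, 3 fell and 8 did not pass (17 rose and 3 fell adjusted over the list alone). The matrix proteases and inhibitors list had a median log2 change of 0.77 (adjusted p = 1.85e-10, and adjusted p = 0.0463 with an estimated correlation). PLAU, the urokinase activator of plasminogen, rose by 1.91 ± 0.11 and the inhibitor SERPINE2 by 3.74 ± 0.12. Of the proliferation genes, 30 of 40 rose, 0 fell and 10 did not pass (31 rose and 0 fell adjusted over the list alone). The proliferation list had a median log2 change of 1.13 (adjusted p = 2.86e-09, and adjusted p = 0.0642 with an estimated correlation). The lists that fell were interferon response and oxidative phosphorylation. Of the interferon response genes, 5 of 35 rose, 15 fell and 15 did not pass (6 rose and 17 fell adjusted over the list alone). The interferon response list had a median log2 change of −0.58 (adjusted p = 0.00278, and adjusted p = 0.129 with an estimated correlation). Of the oxidative phosphorylation genes, 2 of 51 rose, 35 fell and 14 did not pass (2 rose and 37 fell adjusted over the list alone). The oxidative phosphorylation list had a median log2 change of −0.49 (adjusted p = 7.94e-09, and adjusted p = 0.436 with an estimated correlation). PSMB9, an immunoproteasome subunit, fell by 2.22 ± 0.18, and the respiratory chain subunit COX6C by 0.93 ± 0.11. The other 6 lists did not pass. Of the hypoxia and glycolysis genes, 10 of 33 rose and 3 fell (11 and 4 adjusted over the list alone), with median 0.35 and adjusted p = 0.143. Of the cholesterol synthesis genes, 2 of 25 rose and 3 fell (2 and 2 adjusted over the list alone), with median −0.04 and adjusted p = 0.56. Of the immediate early and heat shock genes, 11 of 29 rose and 10 fell (11 and 10 adjusted over the list alone), with median −0.15 and adjusted p = 0.821, its test pointing up. Of the p53 targets, 8 of 25 rose and 3 fell (8 and 3 adjusted over the list alone), with median 0.29 and adjusted p = 0.0682. Of the contractile genes, 5 of 23 rose and 9 fell (6 and 10 adjusted over the list alone), with median −0.42 and adjusted p = 0.541. Of the pericyte genes, 7 of 16 rose and 2 fell (8 and 3 adjusted over the list alone), with median 0.60 and adjusted p = 0.204. In the pericyte list NOTCH3, a receptor of mural cells, rose by 3.59 ± 0.19, and in the p53 list GDF15, a stress cytokine, by 4.29 ± 0.15.

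Of the called genes, 59 had at least 10 times the level in another class. The count was 1868 and 1989 without VMT library 1 and 2, 6285 without monolayer library 1 and 2157 with equal cells per library. With the libraries labelled HCT116 added and library set as a covariate, 1107 genes were called, and 40 of the 70 named genes kept their call, SLC7A11, PSMB9 and COX6C not among them. The interferon and oxidative phosphorylation lists then gave adjusted p = 0.129 and 0.11 (ranges over their alternatives 0.00201 to 0.129 and 6.49e-11 to 0.436), and the hypoxia list passed and rose (adjusted p = 0.00859, range 0.00859 to 0.306).

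In endothelial-like cells, genes of growing and specialised vessels were higher in the VMT than in the monolayer, and genes of cell division were lower. With an estimated correlation the tip, arterial, flow, identity and proliferation lists all lost their call (adjusted p = 0.205 for each). PLVAP (ENSG00000130300), which forms the diaphragms of vessel wall pores, stood at 76.2 ± 14.5 against 1.02 ± 0.14 CPM (log2 fold change 6.01 ± 0.31, adjusted p = 2.05e-30). CD34, a sialomucin of vessel and progenitor cells, stood at 176 ± 39.1 against 8.01 ± 1.96 CPM, and VWF, which carries a clotting factor, at 388 ± 62.7 against 70.6 ± 7.94 CPM. LY6H had no UMI in the monolayers and stood at 75.4 ± 2.25 CPM in the VMT, at least 564-fold higher over a group floor of 3 counts. CDC20, which triggers the exit from mitosis, stood at 9.24 ± 1.95 against 72.8 ± 11.9 CPM, and the metal-binding MT2A at 759 ± 138 against 11375 ± 977 CPM. The lipolysis inhibitor G0S2 fell by 6.47 ± 0.31. In all, 4695 of 11858 genes changed, 2268 higher and 2427 lower in the VMT, and 2594 by 2-fold or more.

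Of the tip and angiogenic genes, 28 of 32 rose, 2 fell and 2 did not pass (29 rose and 2 fell adjusted over the list alone). The tip and angiogenic list had a median log2 change of 1.82 (adjusted p = 1.06e-29, and adjusted p = 0.205 with an estimated correlation). The netrin receptor UNC5B rose by 2.61 ± 0.24 and the hormone STC1 by 2.78 ± 0.22. APLNR, the apelin receptor, had 3 UMIs in the monolayers and 105 in the VMT, a ratio of 141 (exact 95% interval 47.1 to 697). Of the arterial and Notch genes, 14 of 20 rose, 1 fell and 5 did not pass (14 rose and 1 fell adjusted over the list alone). The arterial and Notch list had a median log2 change of 1.04 (adjusted p = 1.47e-08, and adjusted p = 0.205 with an estimated correlation). HEY1, a Notch target, rose by 2.27 ± 0.26. Of the flow-responsive genes, 13 of 19 rose, 1 fell and 5 did not pass (15 rose and 1 fell adjusted over the list alone). The flow-responsive list had a median log2 change of 1.15 (adjusted p = 1.13e-07, and adjusted p = 0.205 with an estimated correlation). KLF4, a factor induced by shear stress, rose by 3.19 ± 0.33, and CYP1A1 by 2.67 ± 0.31. Of the endothelial identity and junctions genes, 18 of 29 rose, 0 fell and 11 did not pass (20 rose and 0 fell adjusted over the list alone). The endothelial identity and junctions list had a median log2 change of 0.74 (adjusted p = 8.89e-09, and adjusted p = 0.205 with an estimated correlation). The transcription factor SOX18 rose by 2.40 ± 0.23 and CALCRL, a peptide receptor, by 2.51 ± 0.22. Of the immediate early and heat shock genes, 16 of 27 rose, 5 fell and 6 did not pass (16 rose and 6 fell adjusted over the list alone). The immediate early and heat shock list had a median log2 change of 1.03 (adjusted p = 1.53e-07, and adjusted p = 0.205 with an estimated correlation). FOSB rose by 3.45 ± 0.22 and ATF3 by 3.37 ± 0.24. Of the ATF4 and unfolded protein response genes, 16 of 31 rose, 0 fell and 15 did not pass (16 rose and 0 fell adjusted over the list alone). The ATF4 and unfolded protein response list had a median log2 change of 0.74 (adjusted p = 0.000127, and adjusted p = 0.384 with an estimated correlation). HERPUD1, which acts in the removal of misfolded protein, rose by 1.66 ± 0.21. Of the interferon response genes, 21 of 39 rose, 0 fell and 18 did not pass (23 rose and 0 fell adjusted over the list alone). The interferon response list had a median log2 change of 0.80 (adjusted p = 0.000191, and adjusted p = 0.384 with an estimated correlation). HLA-B, which presents antigen, rose by 1.22 ± 0.21. Of the NF-kB and chemokine genes, 11 of 22 rose, 4 fell and 7 did not pass (11 rose and 4 fell adjusted over the list alone). The NF-kB and chemokine list had a median log2 change of 0.76 (adjusted p = 0.0121, and adjusted p = 0.474 with an estimated correlation). Of the venous and activation genes, 6 of 14 rose, 3 fell and 5 did not pass (6 rose and 3 fell adjusted over the list alone). The venous and activation list had a median log2 change of 0.32 (adjusted p = 0.0167, and adjusted p = 0.356 with an estimated correlation). The lists that fell were proliferation and oxidative phosphorylation. Of the proliferation genes, 0 of 40 rose, 36 fell and 4 did not pass (0 rose and 36 fell adjusted over the list alone). The proliferation list had a median log2 change of −1.55 (adjusted p = 2.04e-17, and adjusted p = 0.205 with an estimated correlation). CCNB1, a mitotic cyclin, fell by 3.00 ± 0.26. Of the oxidative phosphorylation genes, 0 of 51 rose, 39 fell and 12 did not pass (0 rose and 42 fell adjusted over the list alone). The oxidative phosphorylation list had a median log2 change of −0.81 (adjusted p = 1.58e-13, and adjusted p = 0.415 with an estimated correlation). CYCS, which carries electrons to the last respiratory complex, fell by 1.56 ± 0.21. The other 4 lists did not pass. Of the hypoxia and glycolysis genes, 6 of 32 rose and 11 fell (6 and 11 adjusted over the list alone), with median −0.09 and adjusted p = 0.29. Of the cholesterol synthesis genes, 6 of 25 rose and 7 fell (7 and 7 adjusted over the list alone), with median −0.00 and adjusted p = 0.955, its test pointing up. Of the TGF-beta response genes, 9 of 29 rose and 8 fell (10 and 8 adjusted over the list alone), with median −0.06 and adjusted p = 0.283, its test pointing up. Of the p53 targets, 3 of 26 rose and 8 fell (3 and 8 adjusted over the list alone), with median −0.01 and adjusted p = 0.422.

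Of the called genes, 41 had at least 10 times the level in another class. The count was 3010 and 2096 without VMT library 1 and 2, 2929 with DESeq2 and 3061 with no filter on low counts. With the libraries labelled HCT116 added and library set as a covariate, the interferon, NF-kB and venous lists gave adjusted p = 0.874, 0.981 and 0.379 (ranges over their alternatives 0.000142 to 0.874, 0.00585 to 0.981 and 0.00852 to 0.379).

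**Figure D3:**
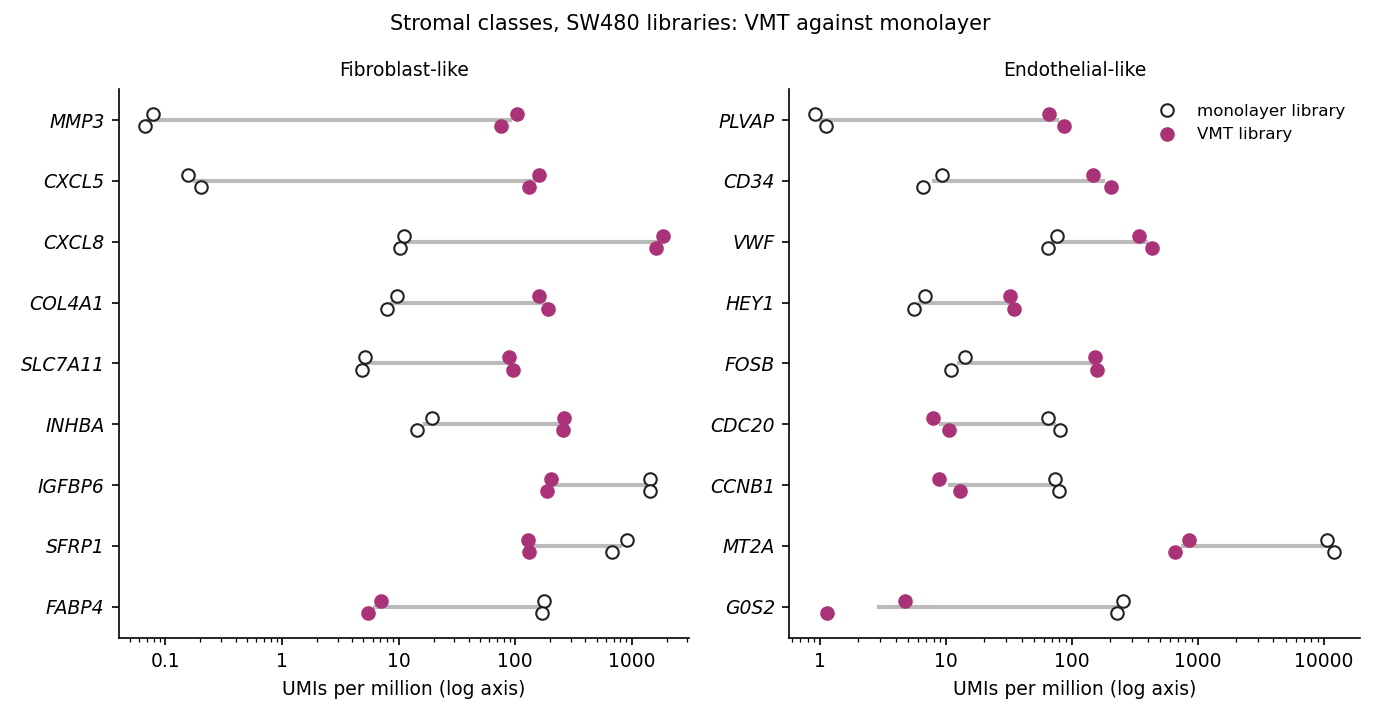
Level of 9 genes in fibroblast-like cells and 9 genes in endothelial-like cells (x axis, CPM on a log scale) in the SW480 library sets, with open points for monolayer libraries, filled points for VMT libraries and a grey line between group means. MMP3, CXCL5 and CXCL8 were higher in VMT fibroblast-like cells, PLVAP and CD34 were higher in VMT endothelial-like cells, and CDC20, CCNB1, MT2A and G0S2 were lower there.

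Whether the classes responded differently to the VMT was tested on the class by culture interaction for the 10 lists run in all classes. Proliferation genes moved apart most. Their median difference was −2.78 on the log2 scale between endothelial-like and tumour-like cells (adjusted p = 7.10e-18) and −2.71 between endothelial-like and fibroblast-like cells (adjusted p = 3.78e-17). With an estimated correlation these gave adjusted p = 0.334 and 0.142. The ATF4 and unfolded protein response list was higher by 1.83 in fibroblast-like than in tumour-like cells (adjusted p = 2.99e-25, and adjusted p = 0.0377 with an estimated correlation). The NF-kB and chemokine list was higher by 1.92 in fibroblast-like cells (adjusted p = 1.42e-07, and adjusted p = 0.0445 with an estimated correlation). Of the 30 tests, 19 passed, and 5 of them, all between fibroblast-like and tumour-like cells, passed with an estimated correlation. The p53 target list did not pass in any of the 3 pairs of classes.

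**Figure D4:**
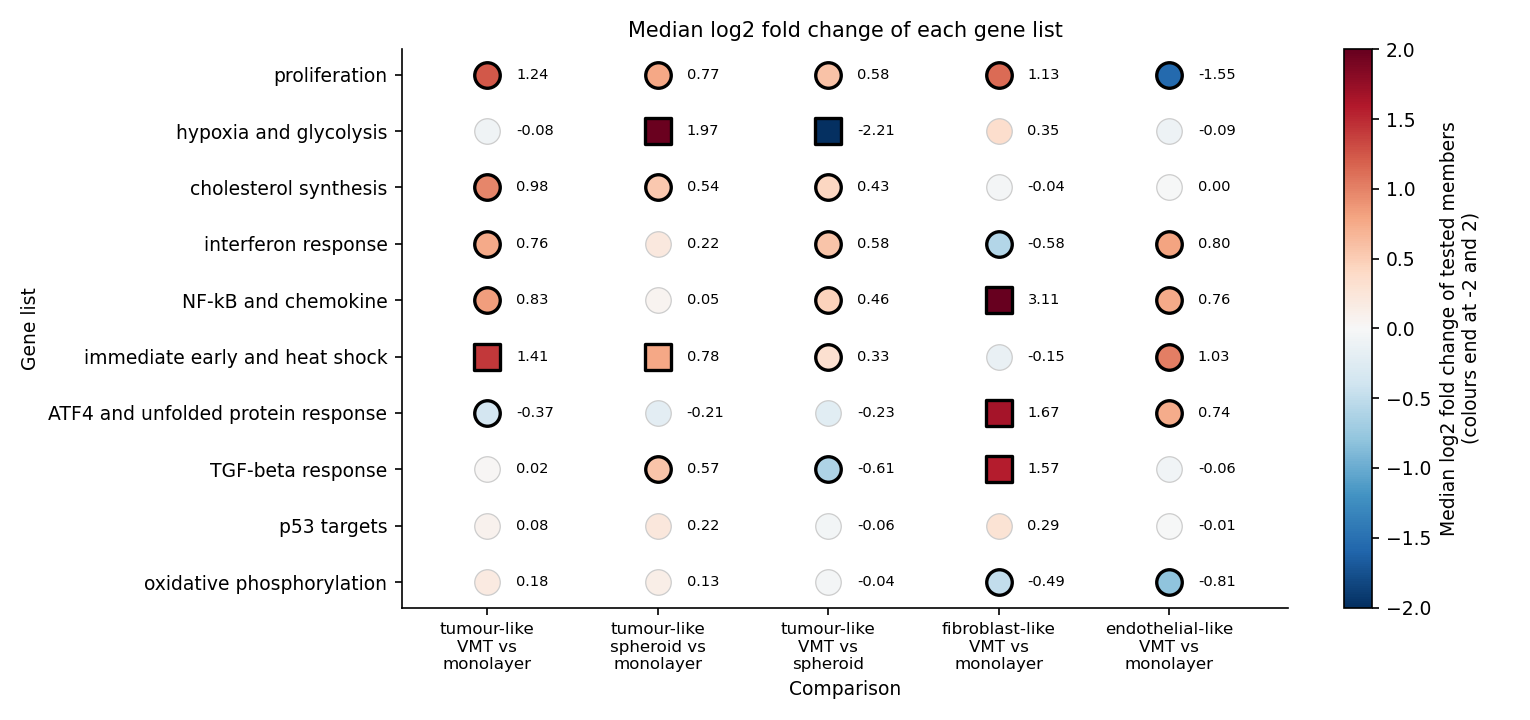
Median log2 fold change (colour, which ends at −2 and 2) of the 10 gene lists run in all classes (y axis) in the 5 tested comparisons (x axis). A black edge marks an adjusted p under 0.05 by camera and a square a call that also holds with an estimated correlation. Hypoxia genes rose in spheroids against monolayers (median 1.97), and the proliferation calls in VMT fibroblast-like (1.13) and endothelial-like cells (−1.55) were lost with an estimated correlation (adjusted p = 0.0642 and 0.205).

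The libraries labelled HCT116, 1 monolayer and 1 VMT, set the same cultures against each other without replicates, so values carry exact Poisson 95% intervals and no test. They form one library set and the SW480 libraries the other. The fibroblast-like monolayer cells differed between the sets. One of their clusters held 1440 barcodes of the monolayer labelled HCT116 against 5 and 4 of the SW480 monolayers. Another held 0 against 657 and 669. In endothelial-like cells PLVAP stood at 133 CPM (122 to 144) in the VMT against 2.39 (1.98 to 2.87), and G0S2 at 2.02 (0.926 to 3.84) against 227 (223 to 231). Of the genes called in the SW480 library sets, 4019 of 4695 (85.6%) went the same way in endothelial-like cells. These were 91.9% of the rises and 79.7% of the falls, where 62.2% of all tested genes were higher in the VMT. In fibroblast-like cells 2415 of 3917 (61.7%) did, 60.0% of the rises and 63.5% of the falls. There 41.8% of all tested genes were higher in the VMT. SAA1, an acute phase protein, stood at 392 CPM (375 to 411) against 0.216 (0.0934 to 0.426), and CXCL5 at 99.2 (90.4 to 109) against 0.189 (0.0761 to 0.39). SAA2 had no UMI in that monolayer and was at least 1370-fold higher in the VMT over a floor of 3 counts. NPTX1, a neuronal pentraxin, stood at 1.73 (0.745 to 3.4) against 96.7 (93.5 to 99.9). In tumour-like cells 2168 of 3787 genes (57.2%) went the same way, 71.4% of the rises and 40.7% of the falls, where 61.2% of all tested genes were higher in the VMT. KRT81, a hair keratin, stood at 107 CPM (103 to 111) against 4.04 (3.45 to 4.7), and the Wnt inhibitor DKK4 at 2.08 (1.57 to 2.71) against 74.8 (72.2 to 77.5). DKK4 was a top gene of a cluster with 704 of its 706 cells in that monolayer and 0 in that VMT library, named tumour-like at a marker sum of 546.1 CPM, near the minimum of 500. For the lists called in the SW480 sets, medians were set against random lists of like expression. They went the same way beyond those in 3 of 7 lists in tumour-like, 5 of 9 in fibroblast-like and 7 of 11 in endothelial-like cells. They went the opposite way beyond those, and opposite to every pair of SW480 libraries, in 2, 3 and 3. In tumour-like cells the ATF4 and unfolded protein response list, which fell in the SW480 sets, also lay above its random lists (median 0.62). The lists that went the same way included tip and angiogenic (median 1.55) in endothelial-like, inflammatory fibroblast (2.83) in fibroblast-like and cholesterol synthesis (1.09) in tumour-like cells.

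The tumour line named by the labels was checked against line genes. Across genes, Spearman's correlation of tumour-like levels was 0.804 to 0.914 between labels within a culture and 0.953 to 0.994 between replicates, and genes are not independent replicates. CDKN1A, a target of p53, stood at 13.7 and 24.03 CPM in the libraries labelled HCT116 and 20.5 to 29.1 CPM in the SW480 libraries. MDM2, another target, stood at 9.32 and 9.6 CPM and at 5.41 to 11.6 CPM. SMAD4, a signal carrier of the TGF-beta pathway that HCT116 is known to keep, was chosen after the values were seen. It stood at 0.508 and 0.372 CPM in tumour-like cells of the libraries labelled HCT116, at 0.18 to 0.579 over all 8 libraries, and at 11.4 to 21.6 CPM in stromal cells. These values go against HCT116 as the line of the tumour-like cells in all 8 libraries, the 4 with conflicting labels included. Directions drawn from the tumour-like cells of the libraries labelled HCT116 are directions of an uncertain line.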

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

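The differences of lists between classes were planned, and the test of SMAD4 in the cells without a class was written before its value was seen. All other tests in this part were chosen only after the results had been seen.

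The change of gene lists from monolayer to VMT differed between classes in the interaction test. For fibroblast-like minus tumour-like cells the median differences were −0.98 for cholesterol synthesis, −1.19 for interferon response, −1.16 for immediate early and heat shock and −0.631 for oxidative phosphorylation. They were 1.92 for NF-kB and chemokine, 1.83 for ATF4 and unfolded protein response and 1.02 for TGF-beta response. For endothelial-like minus tumour-like cells they were −2.78 for proliferation, −0.962 for cholesterol synthesis, 0.982 for ATF4 and unfolded protein response and −1.07 for oxidative phosphorylation. For endothelial-like minus fibroblast-like cells they were −2.71 for proliferation, −0.233 for hypoxia and glycolysis, 1.14 for interferon response and −1.45 for NF-kB and chemokine. In the same pair of classes they were 0.827 for immediate early and heat shock, −0.766 for ATF4 and unfolded protein response, −1.16 for TGF-beta response and −0.244 for oxidative phosphorylation. Of these 19 differences, 5 passed with an estimated correlation, all between fibroblast-like and tumour-like cells. In that pair cholesterol synthesis and oxidative phosphorylation did not pass (adjusted p = 0.082 for each). The 12 differences that involve endothelial-like cells did not pass either, with adjusted p from 0.334 to 0.38 against tumour-like and 0.0638 to 0.368 against fibroblast-like cells.

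In some lists the libraries labelled HCT116 went the opposite way to every pair of SW480 monolayer and VMT libraries, and this difference was not tested. In tumour-like cells the medians in the libraries labelled HCT116 were −0.108 for proliferation and −0.608 for Wnt targets and intestinal stem. In fibroblast-like cells they were −0.643 for proliferation, 0.421 for interferon response and 0.284 for oxidative phosphorylation. In endothelial-like cells they were −1.51 for interferon response, −0.165 for NF-kB and chemokine and −0.319 for venous and activation. The tumour-like cells of that monolayer included the cluster named near the minimum, with 704 of its 706 barcodes there and 0 in that VMT library. Its top genes APCDD1 and DKK4 are in the Wnt list. How far this cluster set the tumour-like medians was not tested.

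In the VMT library labelled HCT116, 305 of 1188 kept cells (25.67%, exact binomial 95% interval 23.2 to 28.3%) lay in a cluster that met no class, and the other 7 libraries held 0 cells of it, which allows shares of up to 0.0557 to 0.363% (3 cells of the total). The cluster had 19 genes at 50 CPM or more that lay under 2 CPM in all 3 classes of that library, which argues against doublets or mixed RNA of these classes. SMAD4 stood at 12.2 CPM there (exact 95% interval 10.3 to 14.3) against 0.372 CPM in the tumour-like and 15.3 and 18.9 CPM in the stromal cells of that library, which argues against a state of those cells. A candidate explanation, cells of a neural crest or melanocytic kind, stayed open, since 8 of 22 listed markers reached 10 CPM, against 2 in tumour-like, 1 in fibroblast-like and 0 in endothelial-like cells. SOX10 stood at 97.95 CPM, S100B at 63.7, MIA at 211 (41.4 in tumour-like cells), CD74 at 1068 and HLA-DRA at 368, while the pigment genes TYR, MLANA and DCT were at 0, and the sort for live cells would not remove such cells.

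With classes taken from each cell's own markers, 215 cells (18.1%) of that library had no class, and 202 cells (17%) against 97 (8.16%) were fibroblast-like.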

How the results depend on the processing

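Fits of 1 tumour-like population, without genes that differ between the monolayer libraries, without low-UMI clusters, without the second monolayer and spheroid libraries, with crossed replicate numbers, and of lists with the library set covariate were chosen after the data had been seen. The other alternatives were set before the data were examined. Of 7329 results for named genes under alternatives, 7119 kept their direction and side of the threshold, 190 no longer passed and 20 reversed. Of 552 for lists, 477 kept both, 52 no longer passed, 23 passed anew and 0 reversed. The difference in each class's share between the SW480 VMT and monolayer libraries kept its direction under all alternatives run. Where 1 library of a group was left, it was assumed to vary like the other groups.

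A 2-fold minimum, which only removes genes, left 1713 of 3802 genes for VMT against monolayer and 2292 of 4751 for spheroid against monolayer in tumour-like cells. It left 2292 of 5161 for VMT against spheroid, 1793 of 3918 in fibroblast-like cells, 2594 of 4695 in endothelial-like cells and 643 of 1621 genes shared by both 3-dimensional cultures. With 1 library left out, the count was 316 to 3865, 3038 to 4475 and 1185 to 6245 in the tumour-like comparisons in that order. It was 1868 to 6285 in fibroblast-like and 2096 to 5936 in endothelial-like cells, and the lowest counts came without a VMT library except in spheroid against monolayer, where the lowest came without spheroid library 1. Such fits have fewer libraries, and why counts rose without some libraries was not tested. Equal cells per library, and so fewer UMIs, gave 3072 genes for spheroid against monolayer and 2157 in fibroblast-like cells. The second tumour-like population alone, with fewer cells, gave 1966, 2996 and 2862. Without the second monolayer and spheroid libraries 6988 genes were called for VMT against monolayer and 8746 for VMT against spheroid. The library set covariate gave 1107 in fibroblast-like cells, and DESeq2 gave 2929 and no filter on low counts 3061 in endothelial-like cells. For these 3 values and the 2 before them the cause was not tested. Besides the lists named under the replicate block and in the report, VMT against spheroid passed for ATF4 and unfolded protein response, p53 targets and epithelial junction in the second population (adjusted p = 5.46e-16, 0.0162 and 0.00789). It passed for mesenchymal state without genes abundant in another class (0.0422), an alternative that left out only genes with higher CPM in the VMT. The ranges over alternatives in that order were 5.46e-16 to 0.877, 0.0162 to 0.695, 0.00789 to 0.877 and 0.0202 to 0.485. Without the second monolayer and spheroid libraries, oxidative phosphorylation passed in tumour-like VMT and spheroid against monolayer (0.000209 and 0.0253, ranges 0.000209 to 0.815 and 0.0253 to 0.816), and p53 targets in fibroblast-like cells (0.0224, range 0.0153 to 0.455). The remaining gains came with fry, which does not compare a list with other genes. An estimated correlation left 10 of 42 list calls and 5 of 19 list differences between classes. In the libraries labelled HCT116, 63.18% of fibroblast-like genes went the same way at 10 CPM or more against 61.65% without a minimum.

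Genes that reversed did so mainly within tumour-like populations, and the cause was not tested. In the second population alone, VMT against monolayer gave log2 changes of −0.42 for GZMB, −0.27 for CDK1, −0.82 for GADD45A, −0.56 for NDUFA9, −0.73 for DKK1 and −0.041 for SNAI2. Spheroid against monolayer gave −0.45 for ISG20, −0.62 for OAS2, −1.23 for CSF2, −0.49 for CXCL8 and −0.76 for DKK1, and VMT against spheroid gave 0.63 for TNFAIP2 and −0.048 for NDUFV1. In the first population alone, VMT against monolayer gave 0.26 for NDRG1 and 0.58 for IGFBP3, and VMT against spheroid gave 1.12 for IFI27 and 0.45 for CLDN7. In endothelial-like cells, the library set covariate gave −0.034 for IFI44L and −0.057 for MX1, and SELE, an adhesion molecule for leukocytes, ranged from −1.99 without VMT library 2 to 6.598 without monolayer library 1.

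With the replicate number as a replicate block, counts were 5305, 5943 and 6580 in the tumour-like comparisons, 3783 in fibroblast-like and 4521 in endothelial-like cells, and 43 list calls. No named gene lost its call, and the only list call that changed was ATF4 and unfolded protein response for spheroid against monolayer, which passed (adjusted p = 0.0448, range over its alternatives 0.000777 to 0.565). Same-numbered libraries deviated together for monolayer and spheroid in tumour-like cells (correlation across genes 0.94), but not for monolayer and VMT (−0.03) or spheroid and VMT (−0.01). In fibroblast-like cells the correlation was −0.105, and the crossed block called 4491 genes. At this depth not all simulated 2-fold changes were recovered, with 68 to 70% in the tumour-like comparisons, 87% in fibroblast-like and 78% in endothelial-like cells. These rates hold for genes at 10 CPM or more in the reference group only.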

Other observations

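All tests in this part were chosen only after the results had been seen.

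The tumour-like clusters were parted into 2 populations by the correlation of their profiles, and the second made up 16.2 to 36.6% of the tumour-like cells of a library. Higher in the second population of all 8 libraries were EPAS1, a transcription factor of the response to low oxygen (43.1 to 167 CPM against 0.708 to 4.03), and KRT5, a basal keratin (49.4 to 622 CPM against 0.659 to 10.8). Higher in the first were the mucosal peptide TFF3 (163 to 1430 CPM against 63 or less) and the keratin KRT7 (156 to 663 CPM against 3.44 to 50.6). These genes were named after their values had been seen. Across genes, the second populations of the monolayers under the different labels correlated at 0.795 and 0.814 (Spearman). The 2 populations within a monolayer gave 0.806 in the library labelled HCT116 and 0.847 and 0.854 in the SW480 libraries. Different populations under different labels gave 0.68 to 0.743. The second populations were not shown to be the same cells under both labels.

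The tumour-like cells of libraries labelled HCT116 and SW480 resembled each other. HCT116 cells in the libraries labelled HCT116 were argued against, since SMAD4, which that line is known to keep, stood at 0.508 CPM at most in their tumour-like cells against 11.4 to 21.6 CPM in stromal cells. One line under both labels stayed open, since within a culture and population 4 to 11 genes in monolayers, but 1 gene in the VMT, were on (50 CPM or more) under 1 label and off (under 2 CPM) under the other, where replicates gave 0 to 1. A mixture of 2 lines in every tumour culture stayed open as well, since 6 to 32 genes were on in 1 population and off in the other, where the unnamed cluster gave 81 to 92. These explanations cannot be told apart from these values, because no library of a known mixture or of a known second line gives their on and off counts.

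The 2 SW480 monolayer libraries differed in the same genes in all 3 classes, with a lowest correlation across genes between classes of 0.9044, and the spheroid libraries differed alike (0.951, 0.91 and 0.911 with the tumour-like, fibroblast-like and endothelial-like monolayer differences). Since the classes were grown apart and combined before capture, this is consistent with a difference between library preparations. The difference also followed transcript length (Spearman's correlation 0.596). Of 4819 genes at a mean of 10 CPM or more in each class, 617 differed one way by at least 0.5 on the log2 scale in every class. All were higher in monolayer library 1, with a median length of 5811 bases against 3105 for the 4819. These differences used CPM without the TMM factors, which were higher for monolayer library 1 than 2 in each class, so scale can add to this direction. Relative to monolayer libraries 1 and 2, the median change of these genes in the VMT was 0.203 and 1.2 in tumour-like cells and 0.082 and 0.956 in fibroblast-like cells. In endothelial-like cells it was −0.0313 and 0.824, and no biological explanation was tested. The genes were picked by the gap between these monolayer libraries, so the gap within each pair of medians was set by that choice.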
